A study of Citrus sinensis with 10 samples.

How the data were processed

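RNA of sweet orange (Citrus sinensis) fruit was compared between Hong Anliu, a red-fleshed bud mutant, and Anliu, its wild type. A bud mutant is a line that arose as a changed shoot on a tree and was kept by grafting. Fruit was taken at 120, 150, 170, 190 and 220 days after flowering. At each time point RNA of the mutant and of the wild type shared an array, once with the mutant in Cy5 and once with the mutant in Cy3, which gave 10 arrays. Per the labels' protocols, 5 µg of total RNA per sample was amplified and then labelled with Klenow enzyme. The labels do not say whether the fruit of a time point was pooled from several trees.

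The arrays carried 19152 spots in 48 printing blocks. Of these, 17568 were cDNA clone spots, from 5856 clones in 61 plates with 3 spots each, and 1584 were controls. A clone is named by plate, row and column. The files do not pair clones with genes, and no clone name matched the gene table at hand, so clones are given by these names and the lists of pathway and cell type genes drawn up beforehand could not be run.

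The authors deposited, for each array, the intensity of every spot in both dyes, per the file headers. These intensities reach below 0 and blank spots centre on 0, so background had been subtracted. The method and the scanner are not given in the sources used here. The deposited array tables also hold a ratio per spot, mutant over wild type on a linear scale. From the values, the authors' series table is the log2 of that ratio, with differences of at most 5e-05. The medians of its 10 columns lie between -0.0417 and 0.0311. The authors' table of lowess ratios lists 5740 of the 5856 clones, with 1 ratio per clone and time point or a blank. Between 75 and 195 clones are blank at a time point, and 5364 have a ratio at all 5. Between 95.0% and 98.9% of the values listed in it lie within 1% of the mean over the 6 spots of the dye-swapped pair.

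The ratios were computed anew from the intensities. Intensities at or below 0 were left out (8 to 33 clone spots per array). The log2 ratio was normalized by a global loess within each array, fitted on the clones with controls at weight 0, and turned to mutant over wild type. The 3 spots of a clone were averaged. A clone was kept where either dye exceeded the 95th percentile of the blank and solvent spots on at least 5 of the 10 arrays, which kept 5852 clones, and 5820 were above it on all 10. The median intensity over clone spots was 1036 to 3959 for the mutant and 2188 to 4556 for the wild type. The number of arrays limits the precision of every value. The loess sets the typical clone to a ratio near 0 on each array, so every ratio is relative to the typical clone of that array. Spots at the top of the scale were kept (0 to 93 clone spots per array).

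The 2 dye-swapped arrays of a time point hold the same pair of extracts and were averaged to 1 replicate, so 5 values entered each fit, 1 per time point. The p-values measure the spread between these 5 collections. limma (version 3.58.1, in R 4.3.3) was fitted with eBayes over the 5846 clones with a value at all time points. Its tests are two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. The first fit tested the mean log2 ratio over the 5 time points, with 4 residual degrees of freedom. The second tested the slope of the log2 ratio on days, with 3 residual degrees of freedom. The third tested the slope of the mean log2 level of both genotypes, after quantile normalization of the levels between arrays. At a single time point no test is possible, and clones were counted that were 2-fold different in the same direction on both arrays. Correlations between time points run across clones, which are not independent replicates.

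On simulated data with the real spread of the 5846 clones, the fit of the mean recovered 37.3% of changed clones at a log2 size of 1, 92.5% at 2 and 98.5% at 4. The slope of the ratio recovered 0%, 0% and 54.5% at slopes of 1, 2 and 4 per 100 days, and the slope of the level 10.4%, 52.2% and 89.4%. False calls numbered 5, 1 and 5. The simulated noise was normal and independent between clones, so these rates do not cover structure that real clones share. Each fit held 67 changed clones of size 1, 67 of size 2 and 66 of size 4 at once. The adjusted p depends on how many clones are changed, so the rates hold for that number only. A lack of calls in the real data thus does not show that no clone changed.

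The rule for named genes, fixed before the data were examined, took the largest changes past the threshold, filled up by clones with the same sign on all 10 arrays, and the most extreme clones of each time point. It asked for a gene name, which no clone has. Its order was therefore applied to clone names and shortened to 2 clones in each direction, or 1 at a time point, with both genotypes above background on both arrays. Clones named outside that order were chosen after their values were seen. The alternatives to these settings were another normalization within arrays, the authors' own ratios, other filters and thresholds, other fits, and arrays or time points left out. The control spots Y1 to Y4 as the centre and a turned sign at 170 days were among those added after the values were seen. The intended mutant to wild type ratios of the controls Y1 to Y8 are not given in the sources used here. Y1 to Y4 are thus not known to be equal in both genotypes.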

Results

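Fruit collections of the red-fleshed mutant and its wild type from 5 time points were compared on 10 dye-swapped cDNA arrays, 2 for each time point. The comparisons ask how far fruit gene activity of the bud mutant departs from that of its wild type, and whether the departure lasts through ripening. The dye-swapped arrays of a time point correlated across clones at r = 0.90 at 120 days, 0.88 at 150 days, 0.97 at 170 days, 0.93 at 190 days and 0.79 at 220 days. The SD of the log2 ratio over clones was 0.61, 0.77, 0.98, 0.71 and 0.66, against a hybridisation SD between the dye-swapped arrays of 0.20, 0.27, 0.18, 0.20 and 0.33. All ratios are mutant over wild type on the log2 scale, relative to the typical clone of the array.

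At every time point between 384 and 1463 of the 5852 clones were 2-fold different on both arrays. At 120 days 212 clones were higher and 304 lower in the mutant, and at 150 days 420 were higher and 325 lower. The count was highest at 170 days, with 465 higher and 998 lower, which is 25% of the clones. The direction at 170 days is in doubt, as an exchange of the genotypes there could not be excluded, and with its sign turned 998 were higher and 465 lower. At 190 days 364 were higher and 281 lower, and at 220 days 256 were higher and 128 lower. The mean of both arrays was 2-fold for 576 clones at 220 days, and the array with the mutant in Cy5 alone gave 437 higher and 372 lower. Between 1 and 4 clones per time point were 2-fold in opposite directions on the dye-swapped arrays. These counts have no biological replicate and no test. The larger side depends on the centre of the ratio at 120 days: 41.1% of the 516 clones were higher, against 59.3% with median centring and 29.6% in the authors' series table. With the arrays centred on the control spots Y1 to Y4 the lower clones were the larger side at 120, 150, 170 and 190 days, and clone 13.E.5, named next, lay at -0.13 at 120 days. The count was then highest at 120 days (5541), with 2813 at 220 days and 1661 at 170 days.

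**Figure D1:**
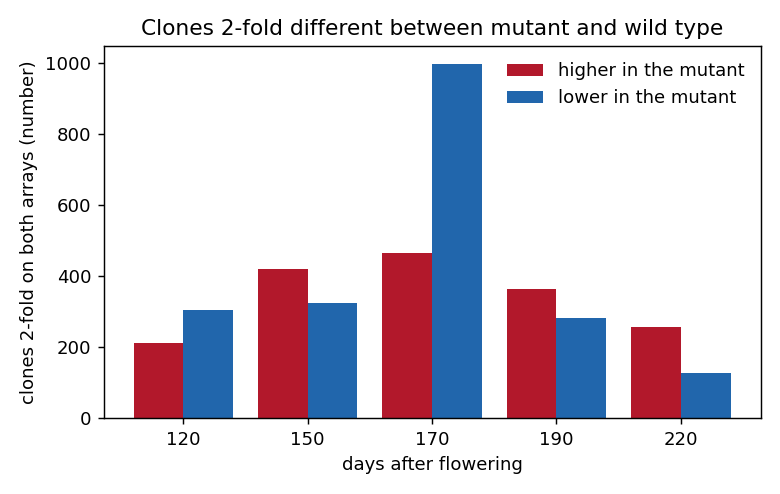
Number of clones at least 2-fold different on both dye-swapped arrays (vertical axis) at each time point in days after flowering (horizontal axis), with separate bars for clones higher and lower in the mutant. The bar for lower clones reaches 998 at 170 days and lies between 128 and 325 at the other time points.

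The clones with the most extreme ratios differed from time point to time point. Clone 9.C.10 had the highest ratio at 150 days (3.18) and at 190 days (4.37). At 120 days clone 13.E.5 stood at 1.89 and clone 28.B.6 at -2.58. Clone 15.H.6 was lowest at 150 days, at -3.07. At 170 days clone 15.G.9 stood at 3.03 and clone 4.H.11 at -4.77. Clone 46.G.10 was lowest at 190 days (-3.87), and at 220 days clone 25.B.5 stood at 2.36 and clone 46.E.10 at -4.01. As labelled, clone 25.B.5 changed sides over time: it stood at -0.90 at 120 days, 2.41 at 150 days and -2.58 at 170 days. It was higher in the mutant again at 190 and 220 days. Both arrays of each time point gave these signs. With the doubted sign at 170 days turned, clone 25.B.5 would be lower in the mutant at 120 days only and higher from 150 days on.

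No clone passed the test of a mean ratio different from 0 over the 5 time points. In limma, 0 of 5846 clones were under an adjusted p of 0.05, and 204 were under an unadjusted p of 0.05, 57 higher and 147 lower, where chance alone would give 292.3. Without 120 days the count at an unadjusted p under 0.05 in limma was 99, with 53 higher and 46 lower. Without 150 days it was 58, without 190 days 97 and without 220 days 595. Without 170 days it was 695, with 403 higher and 292 lower. With the sign at 170 days turned it was 930, with 622 higher and 308 lower. With that at 220 days turned instead it was 895. It was 33, all lower, with a trended and robust eBayes. Clone 31.B.2, chosen after its values were seen, had the smallest adjusted p in limma, 0.398, with a mean ratio of -1.76 (SE 0.23, n = 5 time points). It was the only clone 2-fold lower at all 5 time points as labelled. Among clones with the same sign on all 10 arrays, the highest means were those of 9.C.10, 2.56 ± 1.41 (SD, n = 5), and 14.C.5, 0.84 ± 0.44. The lowest were those of 46.G.10, -2.42 ± 1.47, and 46.E.10, -2.40 ± 1.53. With the sign at 170 days turned, the means of 9.C.10, 46.G.10 and 46.E.10 were 1.41, -1.80 and -1.77. The clones would then no longer have the same sign on all 10 arrays. None of these 4 clones passed the test, with adjusted p in limma of 0.660 for 9.C.10, 46.G.10 and 46.E.10 and 0.976 for 14.C.5. With the ratios centred on the control spots Y1 to Y4, whose intended ratio is not known, 15 clones passed, all lower. Among them were 46.G.10 and 46.E.10 (adjusted p = 0.0132 in limma). On all 10 arrays with the time point as a random block and no replicate block, 1 clone passed, lower, and with the replicate block 0 passed.

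How many clones stayed on the same side depended on the direction at 170 days. Of the 5852 clones, 3594 were never 2-fold different and 1267 were so at a single time point. Another 656 were higher at some time point and lower at another. Clones lower at 2 or more time points and never higher numbered 246, and clones higher at 2 or more and never lower numbered 89. At 4 or more time points 19 clones were lower and 0 were higher. With the sign at 170 days turned, 268 clones changed sides, 209 were lower at 2 or more time points and never higher, and 514 were higher at 2 or more and never lower. At 4 or more time points 10 were then lower and 22 higher.

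A group of 15 clones from 9 plates had both a correlation above 0.97 with clone 46.G.10 over the 10 arrays and a mean ratio below -1.5. It was picked after its values were seen. The first condition was met by 22 clones with or without the second, and the low medians follow in part from that limit on the mean. Its median ratio was -0.40 ± 0.11 (SD over clones) at 120 days, -2.12 ± 0.17 at 150 days, -1.44 ± 0.22 at 170 days, -3.54 ± 0.32 at 190 days and -3.66 ± 0.39 at 220 days. Of the 15 clones, 14 are among the 19 that were lower at 4 or more time points. Whether these clones carry the same transcript is not known from the files.

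The ratios of different time points agreed little, with a mean correlation over the 10 pairs of 0.0270. The closest pair was 150 and 190 days, r = 0.66 (Spearman's rho 0.56) across clones, with 343 clones 2-fold different in the same direction at both, against 41.7 from independent lists, and 1 in opposite directions. In 4 of the 10 pairs r was negative. At 170 days the ratios ran against those of 150 days (r = -0.32), 190 days (r = -0.27) and 220 days (r = -0.51). With 120 days they correlated weakly and positively (r = 0.20). There 169 clones were 2-fold in the same direction, against 68.7 from independent lists, and 67 in opposite directions, against 60.3. Clones 2-fold in opposite directions numbered 340 at 150 and 170 days, 250 at 170 and 190 days and 244 at 170 and 220 days, where independent lists would share 97.5, 84.4 and 53.8. The pair of 120 and 220 days had r = -0.38. Without 170 days the mean correlation of the pairs was 0.193, and without 150 days it was -0.108. With the doubted sign at 170 days turned it was 0.205. Only the pairs of 120 days with 170 days (-0.20) and with 220 days (-0.38) were then negative.

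**Figure D2:**
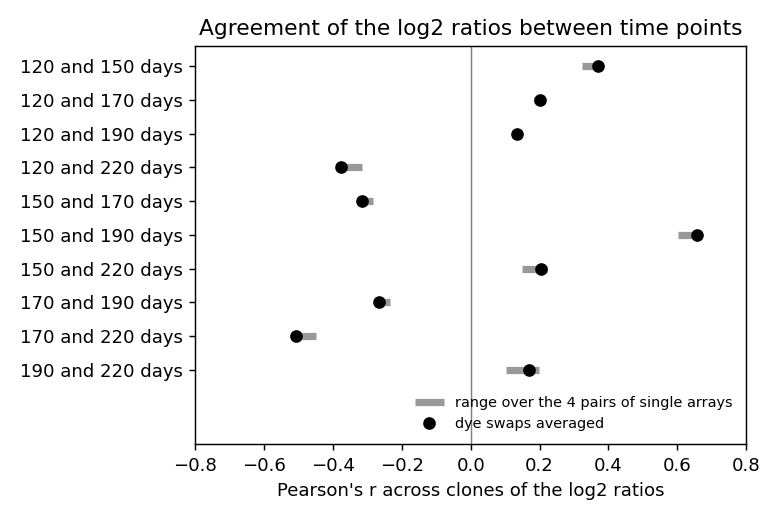
Pearson's r across clones of the log2 ratios (horizontal axis, no unit) for each of the 10 pairs of time points (vertical axis). Points stand for dye swaps averaged and bars for the range over the 4 pairs of arrays: the pair of 150 and 190 days lies at 0.66 and that of 170 and 220 days at -0.51.

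The test of a ratio that rises or falls steadily with time called no clone. In limma, 0 of 5846 clones were under an adjusted p of 0.05, and 414 were under an unadjusted p of 0.05, 265 rising and 149 falling. Without a time point the latter was 118 (120 days, 108 of them rising), 259 (150 days), 764 (170 days), 428 (190 days) or 64 (220 days). With median centring it was 525, with 256 rising and 269 falling. The smallest adjusted p in limma was 0.480, for clone 31.F.6. This count depends on the centre of the arrays. The control spots Y1 to Y4 had a mean log2 ratio of 2.01 ± 0.26 at 120 days (SD over the 4 controls), 0.23 ± 0.16 at 150 days, 0.61 ± 0.22 at 170 days, 0.20 ± 0.14 at 190 days and -1.14 ± 0.24 at 220 days. Centring on them moved the median clone to -1.99 and -2.02 on the arrays of 120 days and to 1.05 and 1.15 on those of 220 days, and then 3448 clones had a rising ratio and 0 a falling ratio. These calls rest on Y1 to Y4 being equal in both genotypes, which is not known.

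**Figure D3:**
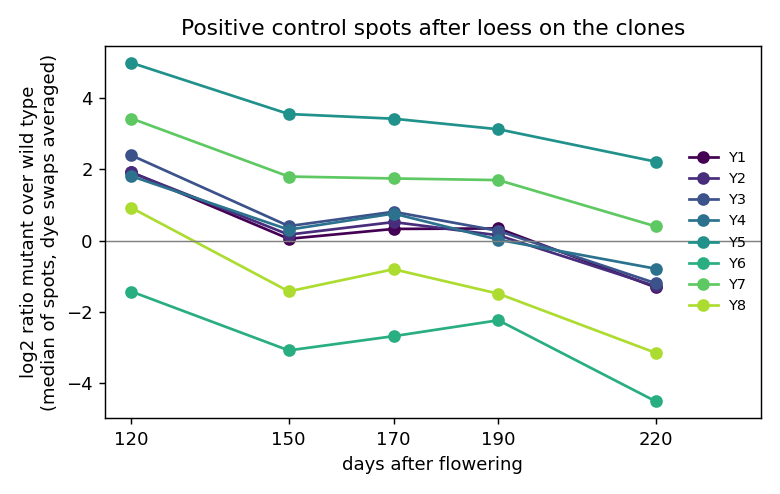
Log2 ratio of the 8 positive controls Y1 to Y8 after the loess on the clones (vertical axis, median of the spots with dye swaps averaged) against days after flowering (horizontal axis), with a line for each control. All 8 lie lower at 220 days than at 120 days.

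The mean level of both genotypes moved with time in 189 of 5846 clones. The arrays differ between time points as well, and the fit cannot tell array differences from development. Of these, 159 rose, with a median slope of 2.52 per 100 days (log2), and 30 fell, with a median slope of -1.66. At an unadjusted p under 0.05 in limma the falling side was the larger, with 600 rising and 719 falling among 1319 clones. The rising side was the larger without 120 days (390 and 297), without 150 days (896 and 874), without 220 days (524 and 422) and with levels set against the control spots (931 and 51). Clone 60.G.1 rose by 3.18 per 100 days (SE 0.30, adjusted p = 0.00989 in limma) and clone 50.A.2 by 3.11 (SE 0.38, adjusted p = 0.00989). The call of 50.A.2 was lost with spots lacking the authors' intensity class left out, where its slope was 0.46 with an adjusted p of 0.541 in limma. Clone 46.G.8 had a slope of -2.40 (SE 0.46, adjusted p = 0.0437 in limma) and clone 44.G.7 a slope of -2.30 (SE 0.41, adjusted p = 0.0333). Neither passed with levels set against the control spots, with adjusted p in limma of 0.0613 and 0.0578, nor without 170 days (0.0962 and 0.0832) or without 190 days (0.0572 and 0.0594). Their slopes were -2.40 and -2.30 without 170 days and -2.12 and -2.07 without 190 days, where the fit had fewer degrees of freedom. Plates 30 to 61 held 143 of the 159 rising and 24 of the 30 falling clones, and 3064 of the 5846 tested.

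Taken separately, 0 of the 159 rising and 2 of the 30 falling clones were ordered in time in both genotypes. All 159 rising and all 30 falling clones still had a slope of that direction in each genotype, though they were picked by the mean of both. The median slope of the rising clones was 2.73 in the mutant and 2.34 in the wild type, and of the falling clones -1.22 and -2.12. In the rising clones the median level of the mutant, relative to each clone's mean, was -1.42 at 120 days, 0.88 at 150 days, -0.61 at 170 days, 1.41 at 190 days and 1.49 at 220 days. In the wild type it was -1.51, -1.41, 0.73, -0.47 and 0.83 at the same times. The slope was steeper in the mutant for 154 of the 159 rising and 7 of the 30 falling clones, a difference that was not tested. With a time point left out, which also leaves fewer degrees of freedom, 0 clones passed without 120 days or without 220 days, 673 without 150 days, 104 without 170 days and 100 without 190 days. The slope of 60.G.1 was 2.88 without 120 days and 3.13 without 220 days, and that of 46.G.8 was -1.91 and -3.42. Of the 189 calls 84.1% were rising, against 54.6% of 302 calls with arrays scaled to the same median level and 99.5% of 210 calls with levels set against the control spots.

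**Figure D4:**
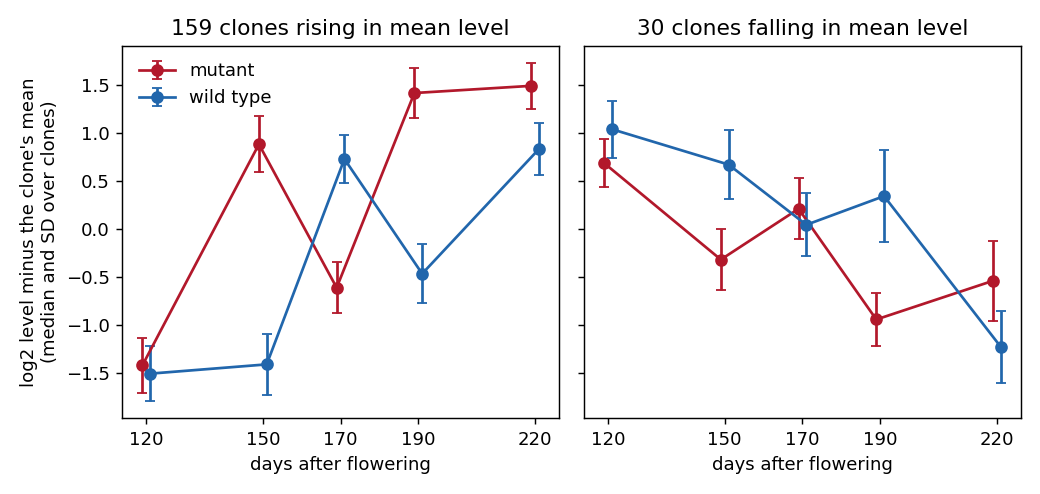
Log2 level minus each clone's mean (vertical axis) against days after flowering (horizontal axis) for the 159 rising and 30 falling clones, with lines for the mutant and the wild type. Points are medians and bars SDs over clones: among the rising clones the mutant lies above the wild type at 150, 190 and 220 days and below it at 170 days.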

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

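The tests of a late exchange of samples, of an early exchange of samples, of developmental stage, of printing blocks, and of all 3 explanations for the control spots were chosen only after the result was seen, or, for the early exchange, given their bound on distinct profiles then. The tests of signal strength, of the plate boundary and of other orders or signs of the time points were set down before their results.

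The number of clones 2-fold lower at 170 days, 998, lies far from those of the other 4 time points. It was the only such value among the profiles of the named clones and the counts over time that were checked (17 sets of 5 values). For independent sets chance would give about 1 in 20, or 0.85 here, so the number of such values is not clearly higher. The sets are not independent, since clones were named for extreme values and the counts share clones. The rate therefore cannot decide whether the 998 arose by chance. Clones 2-fold in opposite directions numbered 340 at 150 and 170 days, 250 at 170 and 190 days, 244 at 170 and 220 days and 96 at 120 and 220 days, and every array pair of these time points correlated negatively. That difference between time points was not tested. The median of plates 1 to 29 lay above that of plates 30 to 61 by 0.151 (log2) at 150 days and by 0.249 at 190 days, and by -0.27 at 170 days, on both arrays each time and without a test of the difference. With the sign at 170 days turned, the last would have the direction of the others, and the 998 would be higher clones.

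For the opposite ratios at 170 days, an exchange of labelled samples after control RNA was added is argued against, since control Y5 exceeded Y6 by at least 5.88 (log2) on both arrays. An earlier exchange of fruit or RNA cannot be told apart from a true difference: of 59 clones 2-fold in the same direction on all 6 arrays of 150, 190 and 220 days, 32.2% kept that direction at 170 days, but by distinct profiles these are 5 of 23 (21.7%, exact 95% interval 7.46 to 43.7). The 5 profiles were grouped anew among the clones that kept their direction. The interval takes the profiles as independent, though at 170 days all rest on the same pair of extracts. The values go both ways, as 22 of the 24 higher clones turned 2-fold lower at 170 days and 19 of the 35 lower clones stayed 2-fold lower. As labelled, the ratios at 170 days also correlated with those at 120 days at 0.20, which an exchange would turn negative. A difference in developmental stage between the fruits remains a candidate explanation, since across clones the ratio correlated with the level slope of the other time points at -0.41 at 170 days and at 0.67, 0.51 and 0.46 at 150, 190 and 220 days, though at 0.08 at 120 days. An exchange at 170 days would also give the opposite sign there, and it leaves the values of the other time points unchanged. Exchanging the genotypes at 170 days lowered the median scatter of the 159 rising clones about a line from 0.889 to 0.576. For the 30 falling clones an exchange at 220 days lowered the scatter more, to 0.375. Over all 5846 clones the scatter was lowest with an exchange at 170 days (0.385 against 0.400). It was 0.394 with an exchange at 220 days and 0.396 at 190 days, and rose with one at 120 or 150 days. An exchange changes the scatter only through the sign of the ratio at that time point. The scatter thus rests on the same opposite ratios and cannot tell an exchange from a true difference.

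For plates 1 to 29 against plates 30 to 61, a difference between printing blocks is argued against as the whole cause, since within the 16 printing blocks that hold both groups the mean difference at 170 days was -0.27 and -0.262 on the arrays (SD 0.18 and 0.20 over blocks). A loess within blocks, the test first set down, left -0.0511 and -0.0573, but it decides nothing: of the 48 blocks 16 hold only plates 1 to 29 and 16 only plates 30 to 61, so it would also remove a true plate difference. Signal strength is argued against by a mean difference of -0.291 (SD 0.13) over 20 bins of level. For a chance boundary, taken from 190 days, the two-sided permutation p over plates was 1e-05, the smallest that 100000 permutations can give. The ratios of 170 and 190 days correlate across the same clones at r = -0.27. A boundary found by chance at 190 days could therefore carry over to 170 days, and this p does not exclude it. Position within a block was not tested. What the plate groups contain is not given in the sources used here, and no biological explanation was tested.

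For the control spots that fall against the clones from 120 to 220 days, the loess is argued against by the ratios before normalization. There the mean change of the controls against the median clone of each array was -3.83. The median clone itself moved from -2.03 and -0.83 on the arrays of 120 days to 0.60 and 0.71 on those of 220 days. Part of that change is therefore a shift of the clones. Saturation is argued against by a change of -2.60 or more in size in every one of the 5 controls without a saturated spot on those arrays. Unequal amounts of control RNA and a changed share of clone transcripts in the labelled RNA cannot be told apart, because either moves the 8 controls together (change -3.20, SD 0.463). No biological explanation was tested.

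Turning the sign of any of the time points gives 16 patterns, too few for a share under 0.05. The actual signs gave 204 clones at an unadjusted p under 0.05 for the mean ratio in limma, 8 of the 16 patterns gave as many, and the highest other gave 1069, several times the actual count, which points to a structure shared by clones. For the slope of the ratio, 19 of 60 orders of the time points gave as many clones as the actual 414, the highest other being 1221, so chance cannot be excluded. For the slope of the level, 2 of 60 orders gave at least the actual 189 calls, a share under 0.05. The other of them, with 150 and 170 days exchanged, gave 419, more than the actual order. The actual order thus gave more calls than most orders. Reordering the days cannot tell development from array differences between time points, so it does not settle whether the calls arose by chance.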

How the results depend on the processing

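Chosen after seeing the data were centring on control spots, the 50 added to every signal, leaving out saturated spots or those without the authors' intensity class, the turned sign at 170 days, leaving out arrays for the 2-fold counts, and every alternative for the correlations. Print-tip loess, median centring and the authors' 2 tables, run on the ratios alone, kept the total counts within 1.5 times, as did the filters and the added signal on ratios and levels. By direction they moved more: median centring gave 392 higher clones at 120 days against 212, and falling levels went from 30 to 74 without spots lacking an intensity class, to 58 with added signal, to 51 with clones above background on all 10 arrays and to 64 with a trended and robust eBayes (251 calls). The 1.5-fold counts were 1416, 1691, 2501, 1592 and 1511 from 120 to 220 days. A single array gave 595 to 809 clones at 220 days, where the rule on both arrays no longer applies, against 576 for the mean of both arrays. For the mean ratio, 15 clones passed with centring on the control spots. The replicate number is the dye orientation: on all 10 arrays 1 clone, lower, passed with no replicate block and 0 with the replicate block, and for the slope of the ratio 0 passed in both. Centring on the control spots gave 3448 clones for the ratio slope, and 5541 clones at 120 days (0.00% higher), 2813 at 220 days (99.3% higher against 66.7%), 1661 at 170 days (4.33% against 31.8%), 908 at 150 days (32.5% against 56.4%) and 699 at 190 days (39.2% against 56.4%), and turned clone 13.E.5 at 120 days to -0.13. For the level slope, scaling to the same median gave 302 calls, and leaving out a time point 0 to 673. The mean correlation went from -0.108 to 0.193 with a time point left out. Turning the sign at 170 days gave -0.20 with 120 days, 0.32 with 150, 0.27 with 190 and 0.51 with 220 days, and a mean of 0.205. Apart from the turned sign and fewer samples, the cause was not tested. No background correction and plain subtraction were not run, since the signals come background-subtracted, and averaging per gene and the gene lists were not run without gene names. By the rule of either dye, signal over background limited few clones: 5820 were above it on all 10 arrays. A genotype alone could still lie at background. At 220 days, with the mutant in Cy5, the wild type limit was 822 at a median intensity of 2265. Clones 50.A.2, 46.G.8 and 44.G.7 were each above background in the wild type on 9 of the 10 arrays.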

Other observations

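Across genotypes the closest profiles did not always belong to the same time point. With each clone set against its mean over all samples, the mutant at 190 days correlated with the wild type at 170 days at r = 0.35 across clones and with the wild type at 190 days at -0.15. The mutant at 220 days correlated at 0.34 with the wild type at 170 days and at 0.12 with that at 220 days. At 120 days the genotypes correlated at 0.40, and the mutant at 170 days correlated with the wild type at 120 days at 0.39 and with the wild type at 170 days at -0.52. Within the mutant, 170 days correlated with 190 days at -0.35 and with 220 days at -0.40. Within the wild type it correlated with 190 days at 0.07 and with 220 days at -0.34. The values that involve 170 days rest on its labels, which the exchange left open above puts in doubt. Each r is a mean over pairs of samples from different arrays. Setting each clone against its mean over all samples makes some correlations negative in any data. Large ratios at a time point also lower the r between the genotypes there. These values describe the profiles and test nothing.

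The ratio of 5258 of 5846 clones (89.9%) differed between time points by more than the dye-swapped arrays did, by limma's F-test at an adjusted p under 0.05. That test compares 5 pairs of extracts against hybridisation error and says nothing of the spread between fruits.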
